A study of Drosophila melanogaster with 18 samples.

How the data were processed

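DRIP-seq was run on 18 samples of S2 cells, in 9 groups of 2, from cells labelled LacZ, hrp36 or hrp48 and from input, RNH- and RNH+ material. Per the labels' protocols, genomic DNA was extracted with phenol-chloroform and sonicated, the S9.6 antibody was used, and libraries were made with a DNA library kit. Per the submitters' processing notes, dm3 was the genome build, and Bowtie2 2.2.2, MACS 1.4.2 and DESeq2 were the tools. The order and role of these tools, the version of DESeq2, the treatment of reads that map to several places, and whether peaks were called per library or on pooled libraries are not given in the sources used here. Reads from repeats have several possible places, and how far regions on U and Uextra share reads was not resolved here.

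The authors deposited 3 tables of regions, 1 per cell group. Region names in each table carry the cell group and the ending Un, so regions are taken to be those found in that group's RNH- libraries. This favours regions whose RNH- signal was high there. Each table gives 6 columns of log2 values, which the authors made as means per group. They were tested on the files as means of log2(normalised count + 1): the mean of back-transformed values never exceeded the base mean with a pseudocount of 1. The columns named Un and Tr are read as RNH- and RNH+. The authors' base mean is a normalised signal per region over libraries, and it was equal, with a difference of 0, at the 9 regions that the hrp48 and LacZ tables list with identical borders and at the 3 of the hrp48 and hrp36 tables. The authors' log2 fold change of Tr over Un in the table's own cell group is shrunken, by the name the authors gave the tables, and comes with its standard error, a Wald score (the stat column, deposited by the authors), a p-value and an adjusted p-value deposited by the authors. The adjusted p-value was not equal to a Benjamini-Hochberg adjustment over the listed regions, with differences of up to 0.138 in the LacZ table, and how it was made is not given in the sources used here. The authors' column of calls has another score of -1, 0 or 1, which the authors deposited and which follows the sign at an adjusted p under 0.1. No counts per library were used here, so depth per library is unknown and no interval of counting error is given.

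Calls are regions with the authors' adjusted p under 0.05, counted by direction. Regions were divided into the arms, pericentromeric parts (2L beyond 22 Mb, 2R below 1.3 Mb, 3L beyond 23 Mb, 3R below 0.4 Mb and X beyond 22 Mb, rounded borders from general knowledge), Het scaffolds, chromosome 4, U, Uextra and mitochondrial DNA. Heterochromatin is all of these but the arms and mitochondrial DNA, and its share of calls was tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 3 tables and both directions. Tables were matched with bedtools 2.31.1 by an overlap of at least 1 base, keeping pairs that were each other's best. Differences between tables were tested with a Wald statistic from both authors' standard errors, a normal approximation, adjusted by Benjamini-Hochberg. On simulated data with 200 changed regions this test found 16% of differences of 1 log2 unit and 72% of differences of 2 over 2165 matched regions of hrp36 and LacZ, 8% and 88% over 3187 of hrp48 and LacZ, and 14% and 71% over 2363 of hrp48 and hrp36. The simulation added differences to the shrunken fold changes with normal noise of their standard errors. Shrinkage itself was not simulated. Within a table, the response of 2 cell groups was compared with the standard error of the table's own group taken for both and scaled by 1.09 (hrp36 table) or 1.10 (hrp48 table), since group means are not shrunken. Intervals of medians are 95% percentile intervals from 2000 bootstrap draws of 100-kb blocks. Base mean and length of calls were compared by a permutation test with 100000 resamples. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.

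Before the data were examined, the tests, the alternatives and the rule for named regions were fixed. The rule takes, in each table, the 5 largest changes each way among called regions with a base mean at or above the table's median, with regions named by position, plus the 10 regions called in all 3 tables with the smallest values of their largest adjusted p. The difference test, the comparison at regions of the remaining table, the raised set and the centring of fold changes were added after the data were seen. Alternatives were other thresholds, a minimum fold change, a filter on base mean, another adjustment, removal of unplaced scaffolds, other borders and another overlap. Gene lists and feature types were planned but not run, since the regions carry no gene names and the reference used here belongs to another build. That reference served only to pair hrp36 and hrp48 with the symbols Hrb87F and Hrb27C. The level of knockdown was not analysed here.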

Results

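The data were a DRIP-seq experiment, in which the S9.6 antibody recovers DNA fragments that carry RNA-DNA hybrids (R-loops and related structures) before sequencing. The material was genomic DNA of S2 cells, a Drosophila melanogaster line of embryonic origin. The cells carried a knockdown of hrp36 or of hrp48, the RNA-binding hnRNP proteins encoded by Hrb87F and Hrb27C. Cells labelled LacZ, a bacterial gene that flies lack, were taken as the control. Each of the 3 cell groups gave 2 S9.6 libraries labelled RNH- and 2 labelled RNH+, read here as without and with a treatment by RNase H, the enzyme that degrades the RNA strand of such hybrids. Signal that fell with RNH+ is therefore the part expected of a hybrid. Signal that did not fall may be what the antibody or the sample carries otherwise, but also hybrid left undigested or a fall too small to resolve. Levels are normalised, so a fall common to all regions could be hidden or make other regions seem to rise. Digestion was not tested here. The 12 S9.6 libraries enter 3 tables of regions, 1 for each cell group, and 6 input libraries (10% of the material) were not used here.

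There were 6477 regions in the LacZ table, 2980 in that of hrp36 and 7735 in that of hrp48. Regions were short, with a median length of 457, 566 and 538 bases in this order. The median normalised read count per region and library (the base mean) was 167.0, 310.5 and 98.2. Total reads per library are unknown, and values of single libraries were not used here, so the standard error of the fold change in the authors' deposited table is the error of each region. Levels are the authors' means per group on a log2 scale, without an SD. With 2 libraries per group, whose independence as cultures is not given in the labels, p-values measure the spread between these libraries, which may be technical. All positions are on the dm3 build, where U and Uextra collect scaffolds that were not placed on a chromosome and are rich in repeats, and where scaffolds with the ending Het hold mapped heterochromatin. The regions have no gene names in the tables, and no annotation of dm3 was used, so they are given by position.

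The first question was where the S9.6 signal of control cells depended on RNase H. In LacZ cells the signal fell with RNH+ at 634 regions and rose at 316, out of 6477, at an adjusted p under 0.05 in the authors' deposited table. The called regions that fell had a median fold change of 2.18 downwards, and those that rose 1.95 upwards. The median over all listed regions was -0.06 on the log2 scale (quartiles -0.45 and 0.31, median standard error 0.34). Calls that fell were found on the chromosome arms (289 of 3441 regions), on Uextra (260 of 2028) and on U (44 of 349). On the Het scaffolds 24 of 451 regions fell and 32 rose.

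Among called regions with a base mean at or above the median of the table, the 5 largest falls and the 5 largest rises of LacZ cells lay on Uextra. In the authors' deposited table the region at 28630631 to 28631053 fell by 2.15 (SE 0.42, adjusted p 3.26e-05), and 28213721 to 28214163 fell by 2.12 (SE 0.47, adjusted p 0.000171). The other 3 regions of the leading falls began at 28549511, 16844755 and 26370719 and had log2 fold changes from -2.09 to -2.04. The leading rise, at 27151909 to 27152205, was 2.64 in the authors' deposited table (SE 0.37, adjusted p 5.74e-09), as the group mean went from 6.21 to 9.12. The next rises began at 24787444, 8900164, 10809828 and 24485437, with log2 fold changes of 2.61, 2.59, 2.54 and 2.52 in the authors' deposited table. On the arms, the falls of smallest adjusted p, chosen after their values were seen, were 2R 10509264 to 10512017, which fell by 1.95 (SE 0.32) in the authors' deposited table, and 2R 4983162 to 4984868, which fell by 1.80 (SE 0.30). Mitochondrial DNA held 1 listed region, from 50 to 15005, that fell by 1.39 (SE 0.35, adjusted p 0.000731) in the authors' deposited table. Recomputing the adjustment over the listed p-values alone left 573 LacZ calls, 399 lower and 174 higher. With fold changes centred on the median of the arm regions (-0.09), an alternative chosen after the data were seen, 325 were lower and 243 higher, a lower share of 57.2%, against 398 and 173 (69.7%) in the same test without centring. Het scaffolds then had 8 lower and 25 higher in place of 13 and 15, and the pericentromeric parts 4 and 9 in place of 9 and 8.

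In hrp36-knockdown cells the signal fell at 1338 of 2980 regions and rose at 159, at an adjusted p under 0.05 in the authors' deposited table. Falls were common in every large part of the genome listed there. They took 155 of 470 regions on the arms, 20 of 49 in the pericentromeric parts of the arms, 50 of 138 on Het scaffolds, 108 of 208 on U and 1003 of 2108 on Uextra. The median log2 fold change over all regions was -0.75 (quartiles -1.50 and -0.06, median standard error 0.37), and called regions that fell did so by a median of 3.05-fold. When fold changes were centred on the median of the arm regions (-0.60), 744 regions were lower and 522 higher, a lower share of 58.8%. The same Wald test and adjustment over the listed regions without centring gave 1480 lower and 193 higher, a lower share of 88.5%, near the 89.4% of the authors' calls. On Het scaffolds the majority turned with centring, with 13 lower and 22 higher, while on the arms 96 were lower and 58 higher and on Uextra 566 and 406. Centring moves every region by the same amount and takes its centre from the arms. Such counts therefore show a dependence on the scale and not which scale is right.

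By the same rule, the region with the largest fall in hrp36 cells was Uextra 16063795 to 16064245, at -3.76 (SE 0.46, adjusted p 4.36e-13) in the authors' deposited table, equal to 13.5-fold. Its group mean fell from 11.27 to 6.98 in hrp36 cells and from 9.52 to 7.12 in LacZ cells. The regions beginning at 11404791, 27225217, 28477424 and 26566201 on Uextra followed, with log2 fold changes of -3.62, -3.55, -3.53 and -3.44 in the authors' deposited table. The 5 largest rises were on Uextra as well, led by 27151776 to 27152229 at 2.28 (SE 0.37, adjusted p 5.86e-08) in the authors' deposited table. That region overlaps the leading rise of LacZ cells. The 4 other rises, beginning at 11946694, 22897893, 9309430 and 9858339, had log2 fold changes from 2.23 to 2.13 in the authors' deposited table. Mitochondrial DNA from 27 to 15007 fell by 1.37 (SE 0.35, adjusted p 0.000651) in the authors' deposited table. Called regions of the 5 large arms, pericentromeric parts included, were deep in hrp36 cells and had a median base mean of 2545 against 347.1 for other regions (permutation test with 100000 resamples, two-sided, p = 1e-05, the smallest it can give). Over the whole table the medians were 336.5 and 278.8 (permutation p = 0.00309).

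In hrp48-knockdown cells the signal fell at 3451 of 7735 regions and rose at 442, at an adjusted p under 0.05 in the authors' deposited table, and the direction differed between parts of the genome. On unplaced scaffolds most calls were falls, with 3050 lower and 178 higher of 5707 regions on Uextra and 338 lower and 37 higher of 606 on U. On the chromosome arms most calls were rises, with 175 higher and 41 lower of 1099 regions. Het scaffolds held 39 higher and 20 lower calls of 234 regions, and the pericentromeric parts 12 and 2 of 81. Without U, Uextra and the mitochondrial regions, 63 calls were lower and 227 higher, so the direction of the majority turned. The excess of rises on the arms depended on the scale: with fold changes centred on the arm median (0.24), 147 arm regions were lower and 99 higher, against 56 and 200 in the same test without centring. Het scaffolds then had 49 lower and 26 higher, and the pericentromeric parts 20 and 10. This centre comes from the same arm regions, so by construction it takes out any shift common to the arms. The counts cannot tell which scale is right.

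**Figure D1:**
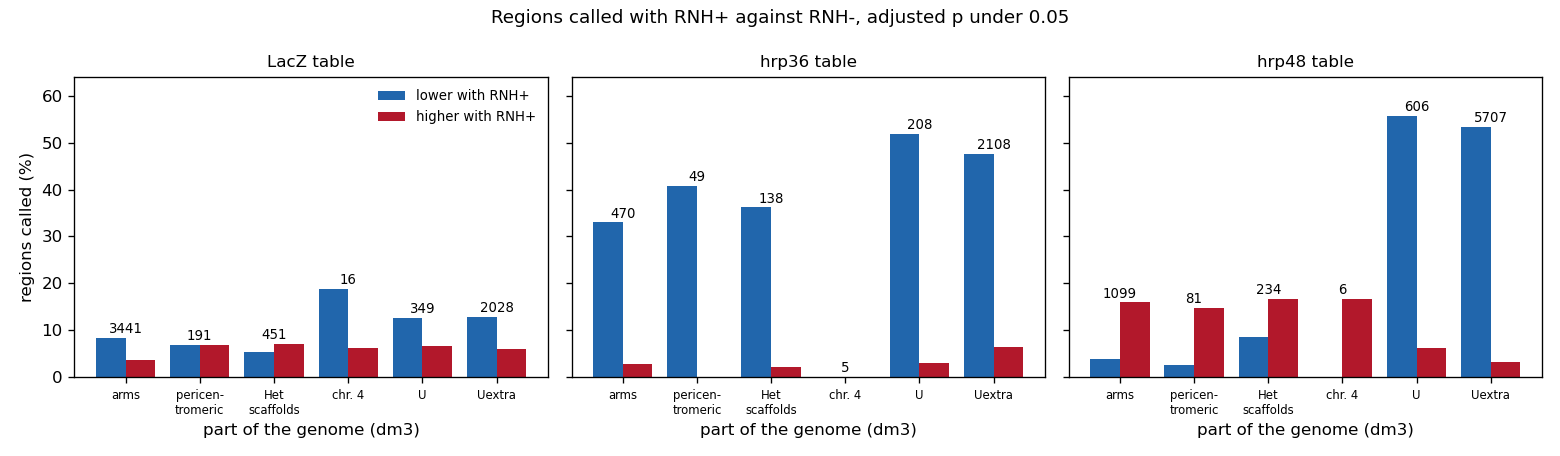
Percent of listed regions called lower (blue) or higher (red) with RNH+ than with RNH- at the authors' adjusted p under 0.05, by table and part of the genome (horizontal axis), with the number of listed regions above the bars. In hrp48 cells 53.4% of Uextra regions fell and 15.9% of arm regions rose, a direction on the arms that turned when fold changes were centred on the arm median (147 lower, 99 higher). By construction, that centre takes out any shift common to the arms.

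The falls of hrp48 cells came mainly from a set of unplaced regions whose RNH- level was higher in hrp48 than in LacZ cells. This set is here called raised. At 3748 of the 6313 U and Uextra regions of this table the RNH- mean was more than 1 log2 unit higher in hrp48 than in LacZ cells, a border chosen after the values were seen. Only 8 of the 6313 regions lay within 0.25 of this border. In the raised set the median difference was 2.28 (quartiles 2.10 and 2.45), a 4.86-fold higher level, against -0.08 at the other 2565 unplaced regions. The median level of the set was lowest in LacZ RNH- (4.59) and highest in hrp48 RNH- libraries (6.87), while the RNH+ medians lay from 5.70 to 6.06. The difference therefore takes in a low LacZ level as well as a high hrp48 level. Of the raised set 2892 regions were called lower with RNH+ and 0 higher in the authors' deposited table from DESeq2, where 3420 were lower and 0 higher at an unadjusted p under 0.05. Of the 3748 regions, 0 overlapped a region of the LacZ table and 2 a region of the hrp36 table, whereas 1930 and 1897 of the other 2565 did. The choice by a low LacZ and a high hrp48 RNH- level favours both the missing overlap with LacZ regions and the falls of hrp48 cells. Neither is therefore separate evidence on the raised set. Outside U and Uextra, such a difference was seen at 13 regions of 3LHet, 10 of them consecutive from 2160538 to 2185380, and at 1 arm region. Without all these regions hrp48 cells had 548 lower and 442 higher calls.

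**Figure D2:**
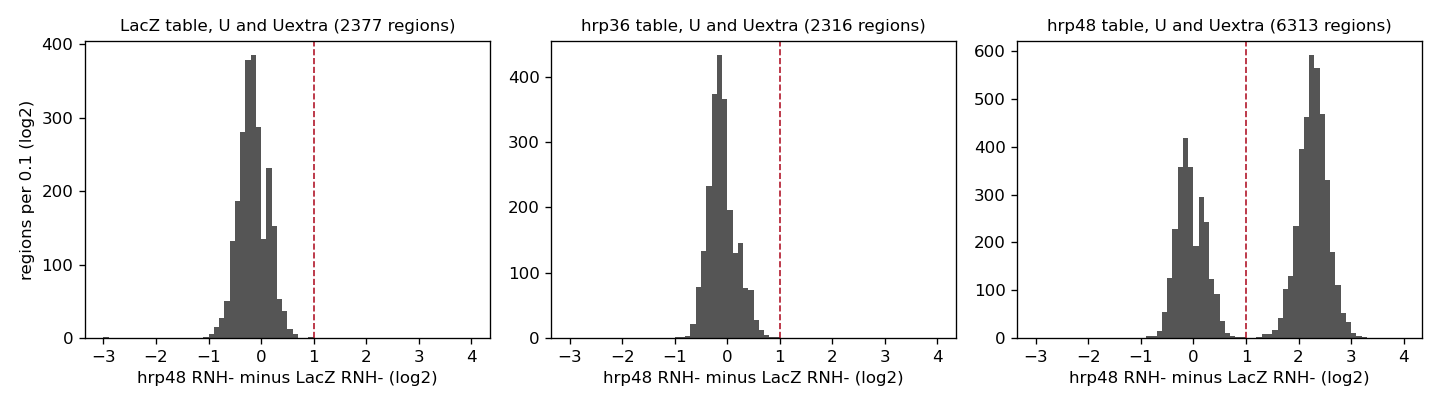
Number of U and Uextra regions (vertical axis, per 0.1 log2) by the difference between the hrp48 and LacZ RNH- group means (horizontal axis, log2) in each table, with the border of 1 dashed. The hrp48 table holds a separate group of 3748 regions around 2.28, which the LacZ and hrp36 tables lack. Regions with a low LacZ RNH- level are unlikely to be listed in the LacZ table.

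In the raised set the median level in LacZ cells was 4.59 with RNH- and 6.06 with RNH+, so that it was higher with RNH+ in control cells, by a median of 1.45, where the LacZ RNH- level had entered the choice of regions. At 3750 unplaced regions chosen without the LacZ libraries, by a hrp48 over hrp36 RNH- difference above 0.5, it was also 1.45. This border too was chosen after the values were seen. Of the 3750 regions, 3745 belong to the raised set, so they are not a second set of regions. In hrp36 cells the medians of the raised set were 5.50 and 5.97, and in hrp48 cells 6.87 and 5.70. At the other unplaced regions the medians of all 6 groups lay between 8.06 and 8.91. Those regions were deeper, with a median base mean of 361.7 against 63.3 in the raised set. Of the 462 with a base mean from the 10th to the 90th percentile of the raised set, 243 were called lower and 10 higher. Their medians with RNH- and RNH+ were 6.305 and 5.302 in LacZ, 6.938 and 5.266 in hrp36, and 6.316 and 5.372 in hrp48 cells.

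**Figure D3:**
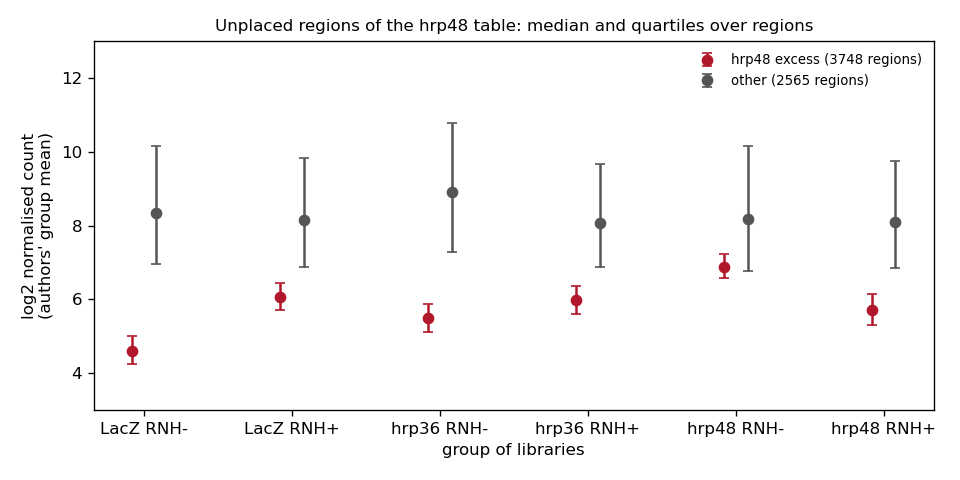
Authors' group means (vertical axis, log2 normalised count) in the 6 groups of S9.6 libraries for unplaced regions of the hrp48 table. Points are medians over regions with bars from the lower to the upper quartile, and the raised set (red) is lowest in LacZ RNH- libraries, at 4.59, and highest in hrp48 RNH- libraries, at 6.87.

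Some leading regions of hrp48 cells overlapped those of hrp36 cells. By the same rule, the largest fall was Uextra 16063820 to 16064202, at -2.53 (SE 0.46, adjusted p 1.26e-05) in the authors' deposited table, at the position of the leading fall of hrp36 cells. Falls at 28696216, 26566212, 28173809 and 7598873 on Uextra followed, from -2.48 to -2.29 in the authors' deposited table. Rises were led by Uextra 14223288 to 14223545, at 2.21 (SE 0.39, adjusted p 7.46e-06) in the authors' deposited table, and the next began at 15380429, 11946807, 22779017 and 13935951, from 2.18 to 2.10. On the arms, the rises of smallest adjusted p, chosen after their values were seen, were 2L 15117837 to 15118063, which rose by 1.74 (SE 0.29, adjusted p 2.60e-06) in the authors' deposited table, and X 20113759 to 20114177, which rose by 1.61 (SE 0.32). The 2R region at 4983164 to 4984701, also chosen after its values were seen, fell by 1.26 (SE 0.30) in the authors' deposited table. Mitochondrial DNA from 52 to 15003 had a log2 fold change of -0.82 (SE 0.35, adjusted p 0.0501) in the authors' deposited table and was not called. The region from 16036 to 17183, at -0.87 (SE 0.45, adjusted p 0.104) in the authors' deposited table, was not called either.

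A second question was whether the same regions responded after each knockdown. Overlap by at least 1 base gave 2165 matched regions between the hrp36 and LacZ tables, 3187 between hrp48 and LacZ, and 2363 between hrp48 and hrp36. Log2 fold changes went together across matched regions, with Pearson's r of 0.788, 0.843 and 0.915 and Spearman's rho of 0.763, 0.839 and 0.910 in that order. These are correlations across regions, which are not independent replicates, since regions on unplaced scaffolds can carry copies of a repeat. Of the matched regions, 287 fell in both hrp36 and LacZ cells, where 138.5 would be found in independent lists (Fisher's exact test, two-sided, odds ratio 18.3, p = 7.54e-81). Rises were shared at 37 regions, against 1.89 (Fisher's exact test, odds ratio 177, p = 5.45e-47). The hrp48 and LacZ cells shared 220 falls against 33.2 (Fisher's exact test, odds ratio 71.9, p = 4.08e-178) and 123 rises against 16.4 (odds ratio 65.9, p = 2.68e-101). The hrp48 and hrp36 cells shared 428 falls against 220.7 (Fisher's exact test, odds ratio 44.6, p = 7.88e-127) and 49 rises against 3.4 (odds ratio 125, p = 6.20e-55). Adjustment over these Fisher tests by Benjamini-Hochberg left the largest p at 5.45e-47. The tests count matched regions as independent, which copies of a repeat are not, so these p-values are too small. Opposite calls were made at 1 matched region, between hrp48 and hrp36, and at 0 with a reciprocal overlap of 50%. That pair joined an hrp48 region of 382 bases, Uextra 24946139 to 24946520, to an hrp36 region of 1107 bases. Over the hrp48 borders the hrp36 group means also fell, from 6.52 to 4.64, so it does not show an opposite response. Matching left out much of the hrp48 table: 42.0% of its regions overlapped a LacZ region, and 0 of the 3748 raised ones did. In that raised set the median change of group means with RNH+ was 1.45 in LacZ and -1.17 in hrp48 cells, a direction that the choice of regions favours.

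**Figure D4:**
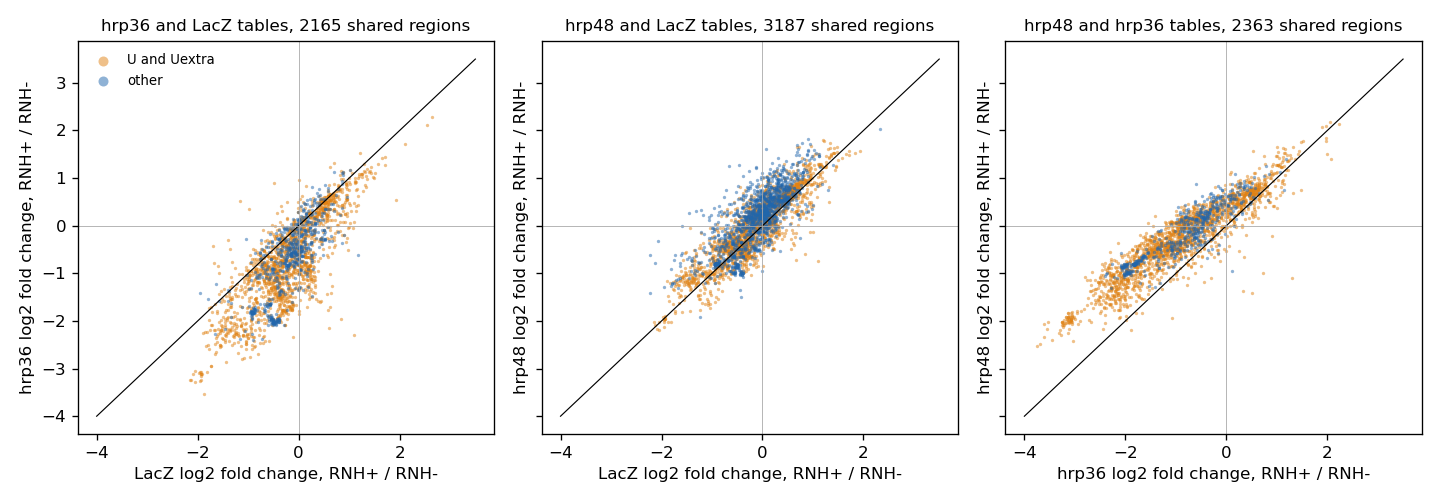
Log2 fold change of RNH+ over RNH- in the authors' tables at regions shared by 2 tables (1 point per region; orange, U and Uextra; blue, all others), with the line of equal values. Points of the hrp36 table lie mostly below the line against LacZ (median difference -0.46), and those of the hrp48 table above it against hrp36 (0.64). Arm regions show such offsets as well (-0.50 and 0.75). The arm medians of the tables (-0.09 in LacZ, -0.60 in hrp36 and 0.24 in hrp48) differ in the same directions, so both offsets depend on the scale.

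Regions listed in all 3 tables numbered 1924, of which 189 fell and 26 rose in all 3 cell groups. Of the 189 falls, 147 were on Uextra, 26 on U, 10 on the arms and 6 on Het scaffolds. The region whose largest adjusted p over the tables was smallest was Uextra 27470765 to 27471243 (borders of the LacZ table), with log2 fold changes in the authors' deposited table of -1.98 in LacZ, -3.09 in hrp36 and -1.91 in hrp48 cells (SE 0.36 in each). Among the 10 leading shared regions, all of which fell, 9 were on Uextra and 1 on U (9794359 to 9794985, with log2 fold changes of -1.76, -2.19 and -1.35 in the authors' deposited table). Each of the 10 fell most in hrp36 cells without centring. The arm medians were -0.09 in the LacZ, -0.60 in the hrp36 and 0.24 in the hrp48 table, so for some of the 10 this order depends on the scale.

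The size of the response was compared region by region with a Wald test of the difference between tables. Between hrp36 and LacZ cells 2 of 2165 matched regions differed after Benjamini-Hochberg adjustment, both on Uextra and both lower in hrp36. At 24808150 to 24808472 the log2 fold change was -2.15 (SE 0.43) in hrp36 and 0.60 (SE 0.43) in LacZ cells in the authors' deposited table (adjusted p of the difference 0.0143). The other, 4795539 to 4796422 in hrp36 cells, was matched to a shorter LacZ region of 269 bases, and over the hrp36 borders the LacZ group means also fell, from 10.54 to 9.11. With a reciprocal overlap of 50% this pair was not matched, and 1 region differed. At an unadjusted p under 0.05 of this Wald test, 337 of the 2165 hrp36 and LacZ regions differed. Between hrp48 and LacZ 0 of 3187 regions differed, with 119 at an unadjusted p under 0.05, and between hrp48 and hrp36 0 of 2363, with 288. On simulated data 4.27% to 4.85% of unchanged regions had such an unadjusted p. Single regions were thus poorly resolved: on simulated data the test found 16% of differences of 1 log2 unit between hrp36 and LacZ and 72% of differences of 2. Those are differences between shrunken values, and shrinkage itself was not simulated.

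As sets, unplaced regions and deep arm regions fell more in hrp36 than in LacZ cells, a comparison chosen after the data were seen. So that regions were not those found in the libraries under comparison, responses (RNH+ minus RNH- group means) were compared at regions of the remaining table. The raised set, whose choice uses the LacZ RNH- level, was left out. At 2565 unplaced regions of the hrp48 table the median response was -0.68 in hrp36 and -0.19 in LacZ cells (median difference -0.40, 95% bootstrap interval over 100-kb blocks -0.47 to -0.32). With the raised set kept (6313 regions) it was -0.79 (-0.82 to -0.75), and with that set chosen and removed without the LacZ libraries (2563 regions) -0.41 (-0.48 to -0.33). Over all 1098 arm regions the median difference was 0.03 (-0.05 to 0.10). At the 182 arm regions with a base mean of at least 1000 it was -0.93 (-1.06 to -0.85), and at the 916 arm regions below this base mean 0.17 (0.10 to 0.23). The base mean takes in the hrp36 RNH- level, so this split is not free of the libraries compared. The RNH- level of hrp36 over LacZ cells was 0.41 at the unplaced regions, 0.72 at the deep arm regions and -0.22 at other arm regions, while the RNH+ levels differed by 0.00, -0.22 and -0.01. The hrp48 response at regions of the hrp36 table exceeded the LacZ response by 0.07 (0.05 to 0.09) at 2316 unplaced regions and by 0.20 (0.15 to 0.27) at 470 arm regions. By depth, it did so by 0.28 (0.19 to 0.34) at 303 arm regions with a base mean under 1000, while at the 167 deeper ones the interval of the difference of 0.13 included 0 (-0.04 to 0.17). These intervals cover the sampling of regions and not the spread between libraries, which cannot be had for a set from group means.

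The series title names heterochromatin, so calls were counted by chromatin part. In LacZ cells falls took 11.3% of heterochromatic regions (344 of 3035) and 8.40% of arm regions (Fisher's exact test, two-sided, odds ratio 1.39, adjusted p = 9.52e-05), and rises 6.23% and 3.69% (odds ratio 1.73, adjusted p = 3.85e-06). In hrp36 cells falls took 47.1% and 33.0% (odds ratio 1.81, adjusted p = 2.70e-08), and rises 5.82% and 2.77% (odds ratio 2.17, adjusted p = 0.00504). In hrp48 cells falls took 51.4% and 3.73% (odds ratio 27.3, adjusted p = 1.71e-237), and rises 4.03% and 15.9% (odds ratio 0.221, adjusted p = 6.92e-42). Without the raised set the hrp48 odds ratios were 5.52 for falls and 0.540 for rises. With U and Uextra left out, so that mapped heterochromatin remained, the odds ratio of LacZ falls was 0.706 (adjusted p = 0.0998), and those of hrp36 and hrp48 falls were 1.17 (adjusted p = 0.624) and 1.90 (adjusted p = 0.0624). The hrp48 value rests on 22 falls among 321 mapped regions, of which 13 falls were on 3LHet. The 13 regions of 3LHet with the raised level were still in this set, and the odds ratio was not computed without them. Rises in LacZ cells then had an odds ratio of 1.96 (adjusted p = 0.00171), with 46 of 658 mapped heterochromatic regions, while those of hrp36 and hrp48 rises were 0.558 (adjusted p = 0.692) and 1.02 (adjusted p = 0.931). The excess of falls in heterochromatin was thus measured on unplaced scaffolds, and neighbouring regions or copies of a repeat are not independent, so these p-values are too small.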

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

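All tests of differences between cell groups and of explanations in this part were chosen after the results were seen. The response to RNH differed between hrp36 and LacZ cells at 2 of 2165 matched regions, both on Uextra, and at 1 with a reciprocal overlap of 50%. Within the hrp36 table it differed at 10 of 2980 regions, each lower in hrp36 cells. These regions are taken to be those found in hrp36 RNH- libraries, whose level is a term of the response, so their choice favours this direction. Over all 2980 regions the median difference from LacZ was -0.53. Within the hrp48 table the response differed from LacZ at 98 of 3987 regions outside the raised unplaced set, 81 higher and 17 lower in hrp48 cells. Of the 17, 13 were among 14 regions outside U and Uextra with the same raised level. This count rests on an adjustment shared with the raised set: over the 3973 regions without any raised level, adjusted alone, the Wald test found 0 (159 at an unadjusted p under 0.05), and leaving those regions out had removed mostly lower values. Of the 3748 raised unplaced regions, 3735 differed, all lower in hrp48 cells, but these regions were chosen by a difference in RNH- level that is itself a term of the response, so the choice fixed the direction and much of the size.

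For the raised RNH- level of hrp48 over LacZ cells at 3748 unplaced regions, noise in the hrp48 RNH- libraries as the whole cause was not settled. In hrp36 cells, whose libraries did not serve to choose the regions, the signal there was higher with RNH+ by a median of 0.51 (at 3590 regions). Levels are normalised, so this cannot be told apart from a rise that regions of little signal share whatever chose them. Hybrids gained after the hrp48 knockdown as the whole cause are argued against by LacZ cells: at 3750 unplaced regions chosen by a hrp48 over hrp36 RNH- difference above 0.5, without LacZ libraries, their signal was higher with RNH+ by a median of 1.45 (at 3749 regions). Of these 3750 regions, 3745 belong to the raised set. A candidate explanation that stays open is a single DNA source present in different amounts in the libraries. The hrp36 response had an SD over the 3748 regions of 0.303, against 1.01 at other unplaced regions of like depth, as a common shift would give. The median standard error of the hrp48 fold change at the 3748 regions was 0.39, while no error of the hrp36 response is given there. The nature of such a source was not tested. Noise as the whole or part of the cause, and a gain of hybrids as part of it, also stay open. So does a low level in the LacZ RNH- libraries, which was not weighed here.

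For the larger fall in hrp36 cells, choice of regions by their hrp36 RNH- level does not account for it at unplaced scaffolds. There, regions found in hrp48 libraries gave a median difference from LacZ of -0.40 without the raised set and -0.79 with it. At arm regions with a base mean of at least 1000 the difference was -0.93. The base mean takes in the hrp36 RNH- level, so this value cannot exclude such a choice there. At the remaining arm regions, with 0.17, the choice is a candidate explanation. A uniformly larger share of unplaced DNA in hrp36 RNH- libraries is argued against because the hrp36 excess over LacZ was largest where hrp48 cells fell most (Spearman's rho -0.578 across 2377 regions, 95% interval -0.604 to -0.549). Among regions with a base mean under 1000 that fell in hrp48 cells, the median excess was -0.32 (-0.37 to -0.18) at 36 arm regions and 0.83 (0.79 to 0.89) at 425 unplaced ones, which argues against a uniformly more efficient pull-down at unplaced regions of this depth, although the rho over unplaced regions has the sign such a pull-down would give. At a base mean of at least 1000 a more efficient pull-down stays open as a candidate explanation, since the excess was larger where hrp48 cells fell more on the arms (rho -0.772 across 198 regions, -0.862 to -0.626) and on unplaced scaffolds (rho -0.571 across 631 regions, -0.686 to -0.447), and at regions that fell in hrp48 cells it was 0.995 at 5 arm regions and 1.13 at 71 unplaced ones. A gain of RNase H-sensitive signal after the hrp36 knockdown may remain, as a hypothesis found and tested on the same 2 libraries per group, and shared reads among repeats were not tested.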

How the results depend on the processing

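Centring of fold changes, removal of the raised set and the test of differences between tables were chosen after the data were seen. No paired analysis was possible because the tables hold group means and their columns carry no replicate numbers, and for this reason no replicate could be left out and no count model was run. Gene lists and feature types were not run. Of the alternatives that could change a value, 56 gave the same direction and the same side of the threshold (for counts, a value within 1.5 times), among them a reciprocal overlap of 50% for correlations between tables and for shared calls. Another 29 took out no region and say nothing about stability: the base mean filter, the merging of overlapping regions, and removal of the raised set where no such region was counted. LacZ calls numbered 950, and 465 at an adjusted p under 0.01, 562 with an absolute log2 fold change of at least 1, 573 with the adjustment recomputed over the listed regions (also with the base mean filter), and 502 without U, Uextra and mitochondrial regions. Centring, which also used a recomputed Wald p and adjustment, gave 568 LacZ calls, against 571 with the same test without centring, so the recomputed adjustment and not the centre lowered this count. The hrp36 calls numbered 1497, and 241 without U, Uextra and mitochondrial regions. The hrp48 calls numbered 3893, and 1480 at an adjusted p under 0.01, 990 without the raised set and 290 without U, Uextra and mitochondrial regions, where rises became the majority; fewer regions were counted there. With a reciprocal overlap of 50%, 1 region differed between hrp36 and LacZ in place of 2. With the pericentromeric parts of the arms as the only heterochromatin, odds ratios were 0.797 (LacZ falls), 1.91 (LacZ rises), 1.4 (hrp36 falls), 0 (hrp36 rises, 0 of 49 regions, 1 at an unadjusted p under 0.05), 0.653 (hrp48 falls) and 0.918 (hrp48 rises), with adjusted p from 0.296 to 0.876. With U and Uextra left out they were 0.706 (LacZ falls), 1.17 (hrp36 falls), 0.558 (hrp36 rises), 1.90 (hrp48 falls) and 1.02 (hrp48 rises). On the large arms alone, called minus other regions in median log2 base mean was -0.28 in LacZ cells (permutation p = 1e-05, the smallest possible; -0.01 over all regions) and -0.048 in hrp48 cells (p = 0.724; -1.41 over all regions), and in median log2 length 0.87 in hrp36 cells (p = 1e-05; 0.03 over all regions) and -0.39 in hrp48 cells (p = 0.00012; 0.18 over all regions). The cause was not tested for any of these. Depth limits arise from 2 libraries per group and a median standard error of 0.34 to 0.38 log2 units per region.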

Other observations

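The loci in this part and the test of base mean classes were chosen after their values were seen. On 2L a stretch from 21417190 to 21538773, where the tandem histone genes lie by general knowledge, held 49 regions of the hrp36 table. Of these 15 fell and 0 rose at an adjusted p under 0.05 in the authors' deposited table, a share no larger than the 33.0% of all arm regions there (155 of 470), with a median log2 fold change of -0.77, near that of all arm regions of the table (-0.60). In LacZ cells 0 of 42 regions there were called by DESeq2, and 0 at an unadjusted p under 0.05 (median -0.10, median standard error 0.34, smallest adjusted p 0.304 in the authors' deposited table), and in hrp48 cells 0 of 23 by either count (median 0.18). The RNH- level of hrp36 cells over LacZ cells had a median of 0.54 over the regions of the hrp36 table, and the hrp48 level one of -0.56. Whether the responses of the stretch differ was not tested across libraries.

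At the distal end of 3R the signal rose. From 27901223 to 27904612 all 4 LacZ regions were higher with RNH+, with log2 fold changes from 0.85 to 0.88 in the authors' deposited table, and all 4 hrp36 regions were, from 0.94 to 1.13. The single hrp48 region there, 27904084 to 27904627, rose by 1.13 in the authors' deposited table (adjusted p 0.00119). Rises on unplaced scaffolds were also common to the cell groups: of 143 U and Uextra regions called higher in LacZ cells, the group means were higher with RNH+ at 138 in hrp36 cells and at 143 in hrp48 cells, with medians of 1.20 and 1.45 against 1.16 in LacZ cells. In hrp36 cells, 100 of 167 arm regions with a base mean of at least 1000 fell (median log2 fold change -1.63 in the authors' deposited table), against 55 of 303 other arm regions (-0.53).

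Mitochondrial DNA carried 4.49% of the summed normalised counts of LacZ-table regions in LacZ RNH- libraries and 1.31% in RNH+ libraries. The shares were 3.47% and 1.27% in hrp36 cells and 4.48% and 1.75% in hrp48 cells.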
